A study of Mus musculus with 6 samples.

How the data were processed

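RNA was sequenced from glomeruli, the filtering units of the kidney, of 6 C57BL/6 mice. Per the labels, 3 Control mice carried loxP-flanked Mafb alleles alone and 3 Mafb-cKO mice also carried Cre-ERT2 under the NPHS2 promoter, a recombinase that acts in podocytes once tamoxifen is given. Mice of both genotypes received tamoxifen intraperitoneally at 75 mg/kg once a day for 5 days at 6 weeks of age. Glomeruli were isolated with magnetic particles 8 weeks later, at 14 weeks of age, and total RNA was extracted. Per the series description each library held RNA of 1 mouse, so the replicates were separate animals, and libraries were sequenced in paired ends on a NextSeq500.

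The deposited values were RPKM (reads scaled by gene length in kilobases and by the read total of the library), 1 file per mouse, as the file headers name them. Each file listed 38924 features by gene symbol, and 35529 of these symbols were also in GENCODE M21. The genome build was mm10 per the submitters' processing notes. The aligner, the read counter, the gene annotation, the strand setting and the treatment of reads with several matches were not given in the sources used here. Genes with near-identical copies, such as H2-Q6 and H2-Q7, and genes that overlap others are therefore uncertain. For 480 features the name carried a number suffix. Magi2 was divided over 3 features, of which Magi2_1 held nearly all of the signal and was used for the gene.

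Sequencing depth was worked out from the values themselves. In each library the RPKM of a feature fell on whole multiples of a step set by the feature's length and the library total. All 15607 features above 0 in all 6 libraries (100%) had a length at which every value was a whole number of reads, with a tolerance of 0.0002 reads plus 3e-09 of the value. For 403 of 755 single-exon genes this length equalled the annotated exon length. The library totals recovered in this way were 20962652, 20892268 and 18337085 reads in Control 1, 2 and 3, and 19934346, 17469973 and 20714505 reads in Mafb-cKO 1, 2 and 3. Reads within the listed features came to 45.2%, 46.4% and 45.0% of these totals in Control, and to 43.2%, 38.6% and 38.6% in Mafb-cKO. Since RPKM was set by the totals and not by the reads in features, a lower share in features lowers the values of a library as a whole. No pair of libraries held identical values.

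The comparison of 3 Mafb-cKO with 3 Control mice was fitted with limma 3.58.1 in R 4.3.3 on log2(RPKM + 1), with genotype as the single term and moderated variances that followed the mean (eBayes with trend). The design written before the data were examined named this test for RPKM and an alternative for raw counts that was not needed. Features with an RPKM of at least 1 in at least 3 libraries were tested, 10735 in all, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are on the log2(RPKM + 1) scale, Mafb-cKO minus Control, which understates the change of low genes. With 3 mice against 3 an exact permutation test of a single gene cannot go below a p of 0.10, so none was used.

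Before the data were examined, 28 gene lists were fixed from textbook knowledge. Of these, 4 covered podocytes (slit diaphragm, cytoskeleton and foot process, transcription factors, identity markers). The others covered the glomerular basement membrane, parietal epithelium, endothelium, mesangium and smooth muscle, macrophages, lymphocytes, proximal tubule, distal nephron and collecting duct, red blood cells, fibrosis, epithelial injury, complement and inflammation, interferon response, cell cycle, immediate early and heat shock genes, unfolded protein response, antioxidant response, retinoid, Notch and Wnt pathways, lipid handling, mitochondrial respiration, ribosomal proteins, the Maf family and sex-linked genes. The 23 lists with at least 5 tested members, sex-linked genes left out, were tested with camera in limma at its preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The preset test compares a list with all other tested features. Counts of members past the threshold were also made with p adjusted over the list alone. Since 2633 of the 10735 tested features were lower at an unadjusted limma p under 0.05, falls counted in this way need not be particular to a list.

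The genes named in the text were chosen by a rule fixed at the same time. It took Mafb, the 12 genes with the largest fold change in each direction among those past the threshold with a mean RPKM of at least 1 and no overlap between the groups, up to 4 members of each list with the smallest p, the sex-linked genes, and Nphs1, Nphs2, Wt1, Tcf21, Magi2 and Synpo. Predicted genes and pseudogenes were counted and not named. Genes outside the rule are said to be so. Coordinates are those of GENCODE M21 on GRCm38, the assembly also called mm10.

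On data simulated from the real means and spreads of 10735 genes, with 200 changed genes in each of 20 runs, the genotype fit recovered 67.8% of 2-fold and 93.8% of 4-fold changes, and 4.78% of its calls were false. With a term for sex it recovered 18% and 79.9%, and 4.4% of calls were false. The fitted log2 fold changes were a median 0.784 of the simulated ones in the genotype fit. A list of 16 genes shifted by -0.7 had an unadjusted camera p under 0.05 in 20 of 20 runs and an unchanged list in 0. The simulated noise was independent between genes, whereas the estimated inter-gene correlation in the data reached 0.87 (endothelial list). These runs therefore do not test the preset correlation on correlated lists. No sex effect was simulated, although the real groups differed in sex. The simulated spreads came from the genotype fit and so hold any sex difference among the Control mice. The shares recovered and the shares of false calls therefore do not carry over to the real calls of either fit.

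The alternatives fixed in advance were the replicate number as a block, each library left out in turn, rescaling by the median ratio to the geometric mean library, quantile normalization, no filter, a mean RPKM of at least 5, limma without the trend and with robust variances, a pseudocount of 0.1, and the mean of the proximal tubule list as a covariate. A pair of alternatives was added after the data had been seen: a term for the sex of the mouse, read from Xist and Ddx3y because the labels do not give sex, and limma-voom on the recovered reads. Tables were also handled with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6, and plots were drawn with Matplotlib 3.10.9.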

Results

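Glomerular RNA of 3 Control mice and 3 mice that had lost Mafb in podocytes (Mafb-cKO) was compared 8 weeks after tamoxifen. Podocytes are the epithelial cells that wrap the glomerular capillaries and build the slit diaphragm of the filter, and Mafb is a transcription factor of the large Maf family that they express. The comparison asks which transcripts of the adult glomerulus differ once Mafb has been deleted there. Library totals recovered from the RPKM values lay between 17469973 reads (Mafb-cKO 2) and 20962652 reads (Control 1), and 10735 features were tested.

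Mafb itself was far lower in the Mafb-cKO mice. It stood at 52.9, 83.8 and 40.7 RPKM in Control 1, 2 and 3 and at 3.08, 3.92 and 4.44 RPKM in Mafb-cKO 1, 2 and 3, from 3758, 5935 and 2528 reads against 208, 232 and 312. The mean fell from 59.1 ± 22.2 to 3.81 ± 0.689 RPKM (SD, n = 3), 6.45% of Control. The log2 fold change was -3.59 (SE 0.26, limma adjusted p = 0.00536), so the values matched the genotype labels in each of the 6 libraries. The gene lies on the minus strand of chromosome 2 at 160363703 to 160367065 (mm10) and has 1 exon. Which part of it the loxP sites flank was not given in the sources used here.

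Nphs1, which encodes the slit diaphragm protein nephrin, and Clic3, a chloride intracellular channel gene, fell as steeply as Mafb. Nphs1 went from 132.9 ± 49.2 RPKM in Control to 9.92 ± 1.64 RPKM in Mafb-cKO (SD, n = 3; log2 fold change -3.56, SE 0.27, limma adjusted p = 0.00536). Clic3 went from 49.0 ± 21.02 to 1.79 ± 0.315 RPKM (-4.07, SE 0.31, limma adjusted p = 0.00536). Nphs1 lies on chromosome 7 at 30458315 to 30487223 on the plus strand, and Clic3 on chromosome 2 at 25456838 to 25458776 on the plus strand.

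Other genes that fell by large amounts were Angptl2, which encodes a secreted angiopoietin-like protein (-2.92), Metrnl, a secreted meteorin-like factor (-2.54), Asb15 (-2.01), Gadd45a, a growth arrest and DNA damage gene (-1.96), and Kcnj12, an inward rectifier potassium channel (-1.92). Their limma adjusted p ran from 0.00644 for Asb15 to 0.0331 for Angptl2. The Qa class I genes H2-Q6 (-3.31) and H2-Q7 (-2.34) fell as well, but these paralogs are so alike that reads could have been divided between them in either way. BC029214 (-2.18), which had no coordinates in the annotation used, and the mitochondrial histidine tRNA mt-Th (-2.15) completed the 12 named genes. For mt-Th the feature is 67 bp long, with 27, 33 and 13 reads in Control 1, 2 and 3 and 3, 4 and 5 in Mafb-cKO 1, 2 and 3. Its call was lost with limma-voom on the recovered reads (adjusted p = 0.0759).

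Among the genes that rose, Fgl2 stood out. It encodes a fibrinogen-like protein with prothrombinase activity, lies on chromosome 5 at 21372642 to 21378374 on the plus strand, and went from 1.07 ± 0.481 RPKM in Control to 22.4 ± 3.04 RPKM in Mafb-cKO (SD, n = 3; log2 fold change 3.51, SE 0.18, limma adjusted p = 0.00134). Nr4a1, an immediate early orphan nuclear receptor on chromosome 15 at 101254269 to 101274795, rose from 2.78 ± 1.10 to 25.5 ± 9.84 RPKM (2.77, SE 0.33, limma adjusted p = 0.0219). Spon2, an extracellular matrix protein gene, was under 0.2 RPKM in every Control mouse and at 8.28, 2.12 and 3.28 RPKM in Mafb-cKO 1, 2 and 3 (2.23, limma adjusted p = 0.0459). Rises of 1.09 to 1.78 on the log2 scale were seen for Ccdc3 (1.78), Sulf2, an extracellular heparan sulfate endosulfatase (1.66), Ntrk3, the neurotrophin-3 receptor (1.64), the receptor-type phosphatase gene Ptprv (1.56), Ajap1 (7.09-fold in mean RPKM), Lsp1, a leukocyte actin-binding protein (1.44), Cyp2s1, a cytochrome P450 (1.30), Gpr182 (1.11) and Wfdc1 (1.09).

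**Figure D1:**
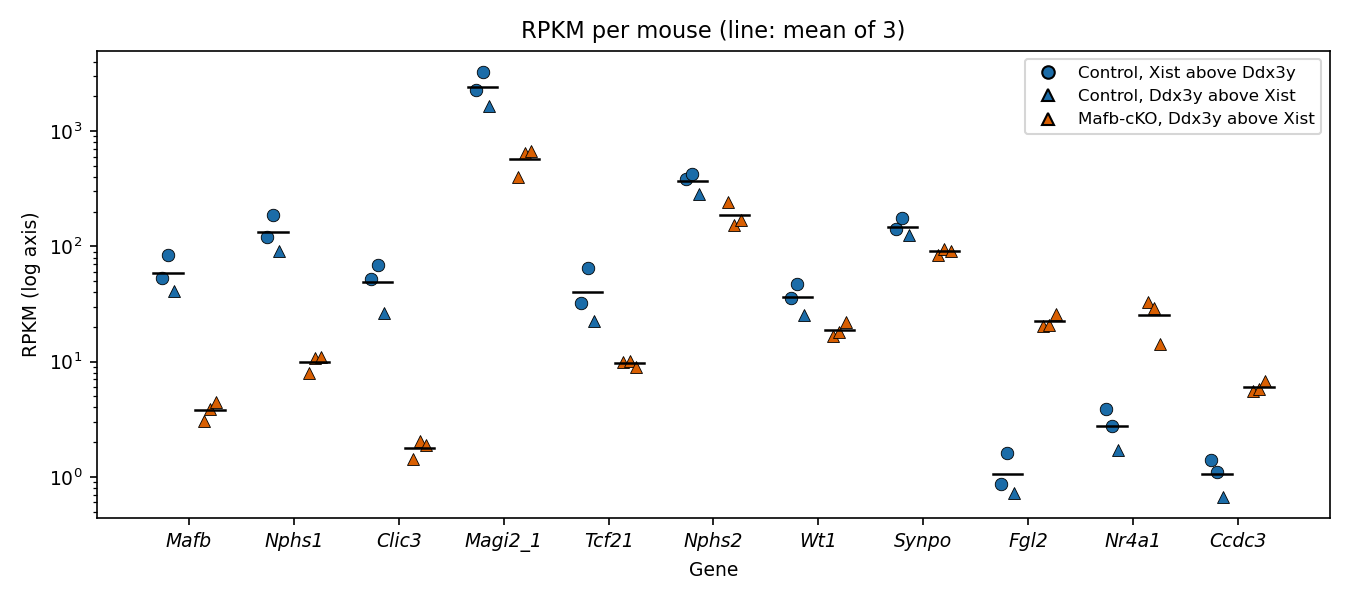
RPKM of 11 features in each mouse on a log axis, with a line at each group mean of 3; blue marks Control and orange Mafb-cKO, and triangles mark libraries in which Ddx3y exceeded Xist. Mafb, Nphs1 and Clic3 were lower in each Mafb-cKO mouse than in each Control mouse by the widest margins, and Fgl2 rose from 1.07 to 22.4 RPKM on average.

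In all, 22 features rose and 79 fell (limma, Benjamini-Hochberg adjusted p under 0.05), of which 3 and 4 were predicted genes or pseudogenes. At an unadjusted p under 0.05, 280 were higher and 2633 lower. The median log2 fold change of all tested features was -0.17, so the deposited values were lower in Mafb-cKO as a whole. After quantile normalization the counts were 26 higher and 32 lower, and after median ratio scaling 27 and 22. Spon2, H2-Q7, Arhgap24 and Pvalb were among the genes that did not pass after either, with limma adjusted p of 0.0592 to 0.0937. Their log2 fold changes after median ratio scaling and quantile normalization were 2.33 and 2.16 for Spon2 (2.23 before), -2.12 and -2.09 for H2-Q7 (-2.34), -0.79 and -0.74 for Arhgap24 (from 19.2 to 8.98 RPKM before) and -1.33 and -1.34 for Pvalb (-1.50). All 101 called features had no overlap between the groups, which their choice by a small p makes likely. Of all tested features 34.0% had no overlap, against 10% by chance. Leaving out any 1 library moved at least 1 of the counts by over 1.5 times: to 6 higher and 5 lower without Control 1, 13 and 24 without Control 2, 168 and 1160 without Control 3, 15 and 13 without Mafb-cKO 1, 6 and 4 without Mafb-cKO 2, and 10 and 13 without Mafb-cKO 3.

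The sexes of the mice, which the labels do not give, were unevenly spread over the groups. Xist, the transcript of the inactive X chromosome, stood at 77.9 and 77.6 RPKM in Control 1 and 2, at 1.65 RPKM in Control 3 and at 0.00280, 0 and 0 RPKM in Mafb-cKO 1, 2 and 3. The Y-linked Ddx3y was listed at 0 in Control 1 and 2, at 6.59 RPKM in Control 3 and at 7.29, 6.55 and 7.28 RPKM in Mafb-cKO. Eif2s3y, Kdm5d and Uty divided the libraries in the same way: they reached 4.49, 3.47 and 3.02 RPKM in Control 3 and at most 0.0349 RPKM (Kdm5d in Control 1) in Control 1 and 2. Control 1 and 2 thus carried the transcripts of females, and Control 3 and all Mafb-cKO mice those of males. The counts without Control 3, 168 higher and 1160 lower, therefore set females against males and cannot separate genotype from sex. In a fit with a term for sex, added after the data had been seen, the genotype difference rests on Control 3 against 3 Mafb-cKO mice. It called 3 features higher (Fgl2, Ccdc3 and Cyp2s1) and 2 lower (Clic3 and Xist), while 811 had an unadjusted p under 0.05. The Xist call rested on 540 reads in Control 3, 2.12% of the level in Control 1 and 2, and the source of these reads was not settled. Mafb was then at -3.12 (SE 0.29, limma adjusted p = 0.0514) and Nphs1 at -3.08 (SE 0.30, limma adjusted p = 0.0561), the highest p of these genes over the alternatives tried, whose lowest were 0.00166 and 0.00184. All 101 features kept their direction with an unadjusted p under 0.05, at a median of 0.825 of their size without the term, but they had been chosen in a fit that used Control 3 as a Control.

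**Figure D2:**
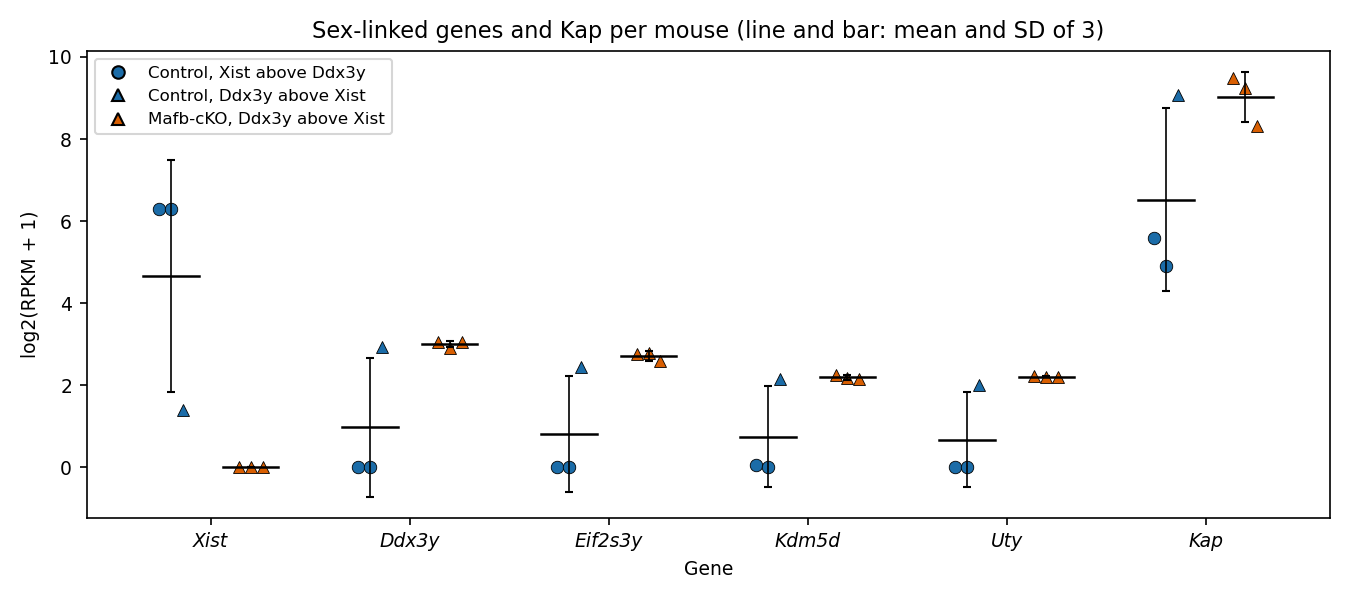
Xist, 4 Y-linked genes and the kidney androgen-regulated gene Kap in each mouse as log2(RPKM + 1), with the mean and SD of each group of 3. Control 3 (blue triangle) carried the Y-linked transcripts that stood at 0.0349 RPKM or less in Control 1 and 2 (blue circles), and its Kap value, 541 RPKM, lay with those of the Mafb-cKO mice.

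**Figure D3:**
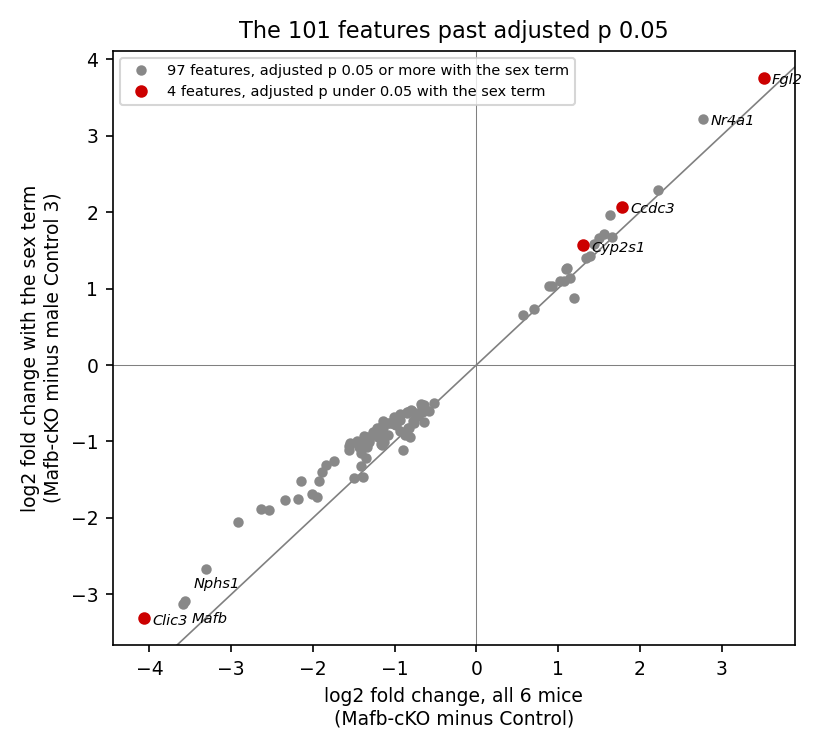
Log2 fold change of the 101 called features in the fit of all 6 mice (horizontal axis) and in the fit with a sex term (vertical axis), with a line where both are equal. All lie in the quadrants of equal sign, and the 4 in red pass the threshold in both fits.

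Of 62 tested members of the 4 podocyte lists, 50 had a negative and 12 a positive fold change, none of the lists passed as a set, and 2 members fell by the test over all genes: Nphs1, and Arhgap24, a podocyte Rho GTPase-activating protein gene (19.2 ± 3.45 against 8.98 ± 0.862 RPKM, SD, n = 3, limma adjusted p = 0.0422). Of the 61 members other than Nphs1, 12 were positive in this fit and 24 with the sex term. Their median of -0.39 stood beside -0.17 for all tested features and -0.56 for the endothelial list, in which 14 of 16 members were negative. In the slit diaphragm list 1 of 14 tested members fell over all genes and 5 fell when adjusted over the list alone, with 14 of 14 negative. The 5 were Nphs1, the scaffold gene Magi2 (feature Magi2_1, -2.04), the adaptor gene Nck2 (-0.91), Nphs2, which encodes podocin (-0.96), and the atypical protein kinase C gene Prkci (-0.54). Magi2_1 was the most abundant of these, at 2288, 3264 and 1650 RPKM in Control against 403, 647 and 679 RPKM in Mafb-cKO, and its limma adjusted p over all genes was 0.0555. Magi2 lies on chromosome 5 at 19227036 to 20704792, and the feature's recovered length of 7629 bp is shorter than the 11348 bp of its annotated exons. As a set the slit diaphragm list did not pass (camera adjusted p = 0.0642, and 0.802 with an estimated correlation). It did pass in some alternatives. Without single libraries its camera adjusted p ran from 0.024 to 0.150, and the lowest over all alternatives was 0.00117. The list median of -0.31 became -0.14 with the sex term, near the -0.11 of all tested features in that fit. Magi2_1 was then at -1.55.

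Among podocyte transcription factors, 0 of 12 tested members passed over all genes and 5 fell when adjusted over the list alone, among them Tcf21, Wt1, Lmx1b and Foxd1. Tcf21 was at 32.4, 65.1 and 22.6 RPKM in Control and at 9.84, 10.2 and 8.96 RPKM in Mafb-cKO (log2 fold change -1.81, limma adjusted p = 0.0602). Wt1 was at 36.1 ± 11.1 against 18.9 ± 2.77 RPKM (SD, n = 3; -0.86, limma adjusted p = 0.104), Lmx1b at -0.63 and Foxd1 at -0.89. In the cytoskeleton and foot process list 1 of 16 members fell over all genes, and over the list alone 6 fell and 1 rose. The actin-associated Synpo, at 148.1 ± 24.5 against 90.4 ± 5.16 RPKM (-0.70, limma adjusted p = 0.104), Ezr (-0.77) and Plce1 (-0.90) were among the 6, and the member that rose over the list alone was Dag1, which encodes dystroglycan (0.67), named here after its values were seen. Of 20 podocyte identity markers 0 passed over all genes and 3 fell over the list alone: the aminopeptidase gene Enpep (-1.52), the guidance receptor gene Robo2 (-1.14) and Thsd7a (-1.18). Ildr2 of the same list was at 34.7 ± 11.7 RPKM in Control and 58.8 ± 3.74 RPKM in Mafb-cKO (0.79, limma adjusted p = 0.119). The camera adjusted p of these 3 lists were 0.521, 0.591 and 0.589. With the sex term the identity list was called with the direction up, against the other features (camera adjusted p = 0.0355, and 0.726 with an estimated correlation), while its median was -0.15. Nphs2 was at 366 ± 75.1 against 188.1 ± 46.4 RPKM (limma adjusted p = 0.106). Control 3 was the lowest of the Control mice for Tcf21, Nphs2, Wt1 and Synpo. With the sex term Tcf21 was at -1.15, Nphs2 at -0.61, Wt1 at -0.42, Synpo at -0.49, Lmx1b at -0.38 and Foxd1 at -0.36.

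**Figure D4:**
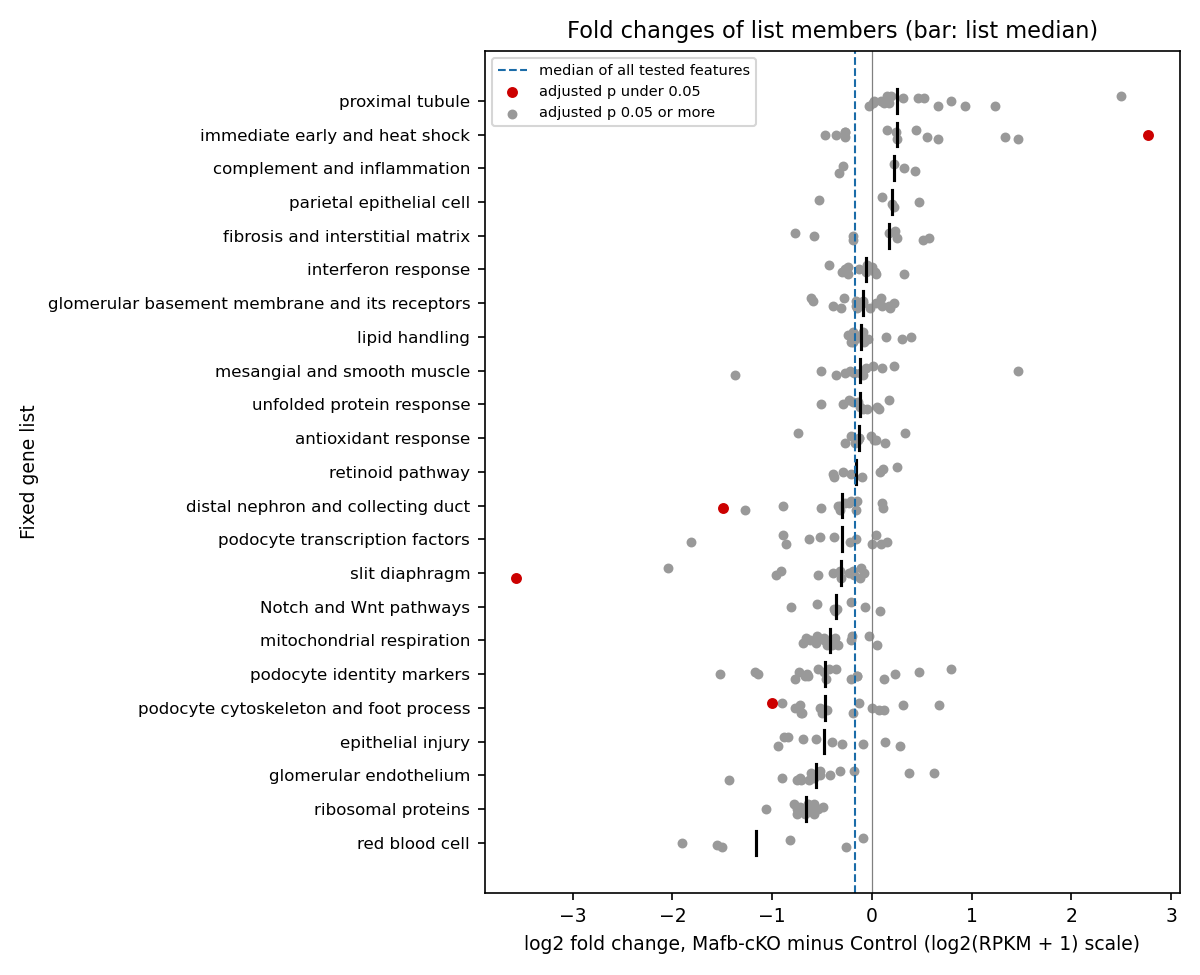
Log2 fold change of each tested member of the 23 fixed lists that were tested as sets, with a black bar at the list median, red points for members with adjusted p under 0.05 and a dashed line at the median of all tested features, -0.17. Slit diaphragm genes reach from -3.56 to -0.07, and the 15 ribosomal protein genes lie close together around -0.66.

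Markers of the other glomerular cells did not pass as sets, and 0 of their members passed over all genes. In the endothelial list, 16 tested, the tissue plasminogen activator gene Plat was at 246.6 ± 46.5 RPKM in Control and 92.4 ± 28.1 RPKM in Mafb-cKO (-1.43, limma adjusted p = 0.0584) and was the 1 member that fell over the list alone. Kdr, the VEGF receptor gene, was at -0.90, Egfl7 at -0.75 and Sost at 0.62 (camera adjusted p = 0.521). In the mesangial and smooth muscle list, 13 tested, the contractile gene Tagln rose over the list alone (1.47, limma adjusted p over all genes = 0.0587), the renin gene Ren1 fell over the list alone (-1.37) and Rgs5 was at -0.51 (camera adjusted p = 0.197). Of 17 basement membrane genes 0 passed either way, with Itga3 at -0.61 and Hspg2 at -0.59 (camera adjusted p = 0.197). With the sex term Itga3 was at -0.16, Hspg2 at -0.14 and the list median at 0.10, against a median of -0.09 without the term. Of 5 parietal epithelial markers 0 passed either way, with Ncam1 at -0.53, Pax8 at 0.47 and Cldn1 at 0.22 (camera adjusted p = 0.0642). Macrophage markers were few, with 4 of 15 above the filter and 0 past the threshold: the colony-stimulating factor receptor gene Csf1r was at 0.88 (limma adjusted p = 0.121), Mrc1 at -0.28, and Lyz2 reached 35.7 RPKM in Mafb-cKO 3 against at most 7.73 RPKM elsewhere. Of 12 lymphocyte markers 0 were above the filter.

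Among stress and injury lists, immediate early and heat shock genes were higher as a set (camera adjusted p = 1.14e-05, and 0.802 with an estimated correlation), with 1 of 14 members, Nr4a1, past the threshold over all genes and 3 that rose over the list alone. The other members past the list-alone threshold were the transcription factor genes Fos (0.66) and Egr1 (0.44). Ier3 was at -0.47. The heat shock genes Hspa1a and Hspa1b, named after their values were seen, reached 76.2 and 158.4 RPKM in Mafb-cKO 1 and at most 14.3 and 23.0 RPKM in any other mouse. Of 10 epithelial injury genes 0 passed over all genes, and the keratin gene Krt7 (-0.94) and Anxa1 (-0.84) fell over the list alone, while S100a6 was at -0.40 (camera adjusted p = 0.591). No member passed either way among 9 fibrosis genes (Thbs1 at -0.77, Sparc at -0.58, Col1a2 at 0.52, camera adjusted p = 0.0642), 5 complement and inflammation genes (Cfb at 0.43, Cfh at -0.33, camera adjusted p = 0.0642) and 13 interferon response genes (Ifi44 at -0.43, Ifit1 at 0.32, camera adjusted p = 0.197). The same held for 11 unfolded protein response genes (Pdia4 at -0.51, Atf4 at -0.29, camera adjusted p = 0.414), 12 antioxidant genes (Gsta2 at -0.74, Prdx1 at -0.27, camera adjusted p = 0.430), 8 retinoid pathway genes (Dhrs3 at -0.39, Rarg at -0.29, camera adjusted p = 0.414), 8 Notch and Wnt genes (Sfrp1 at -0.81, Hes1 at -0.55, camera adjusted p = 0.589) and 13 lipid genes (Hmgcr at -0.24, Apoe at 0.39, camera adjusted p = 0.138). Of 3 tested cell cycle genes 0 passed over all genes, with Mcm6 at -0.23, and Pcna (-0.54) fell over the list alone. Of 4 tested Maf family genes 0 passed either way, with Mafk at -0.46 and its partner Bach1 at -0.30. The basement membrane, mesangial, interferon, unfolded protein, antioxidant, retinoid and lipid lists had negative medians and means while camera gave their direction as up, because camera compares a list with the other tested features, most of which were below 0.

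Transcripts of the renal tubule were measured in the same isolates. The proximal tubule list was higher as a set (camera adjusted p = 6.18e-08, and 0.802 with an estimated correlation), with 15 of 16 members positive and 0 past the threshold either way. The list mean of log2(RPKM + 1) was 4.31 and 3.98 in Control 1 and 2, 4.98 in Control 3 and 5.31, 5.03 and 4.46 in Mafb-cKO 1, 2 and 3. Mafb-cKO 3 thus lay nearer to Control 1 than to Control 3, and sex was not separated from the amount of tubule in the isolates. Single members divided the mice by sex: Kap was at 47.1 and 29.1 RPKM in Control 1 and 2, at 541 RPKM in Control 3 and at 715, 610 and 320 RPKM in Mafb-cKO (2.50, limma adjusted p = 0.169), and with the sex term it was at -0.06. Acsm2 (1.23) and Slc27a2 (0.79) were divided in the same way and stood at 0.05 and 0.14 with the sex term, and the list as a set had a camera adjusted p of 0.205 there. In the distal nephron and collecting duct list 1 of 14 members fell over all genes. That was Pvalb, the parvalbumin gene of the distal convoluted tubule, at 4.90, 7.77 and 6.08 RPKM in Control and 1.88, 1.82 and 1.02 RPKM in Mafb-cKO (-1.50, limma adjusted p = 0.0269). Calb1, which encodes calbindin, also fell over the list alone (-1.27), and Slc12a3, the sodium-chloride cotransporter gene of that segment, was at -0.89 and Wnk1 at -0.33. The list as a set did not pass in the fit of all 6 mice (camera adjusted p = 0.591). Its median was -0.30 there and -0.80 with the sex term, against -0.11 for all tested features with that term. Of 6 red blood cell genes 0 passed over all genes and Hbb-bs fell over the list alone (-1.90), with Hba-a2 at -1.55. The globin genes are near copies of one another, and Hbb-bs was at 30.2, 6.82 and 23.6 RPKM in Control and 2.97, 4.71 and 4.08 RPKM in Mafb-cKO (camera adjusted p of the list = 0.197).

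Ribosomal protein genes were lower as a set (camera adjusted p = 8.28e-06, and 0.802 with an estimated correlation), with 0 of 15 members past the threshold over all genes, 15 of 15 that fell over the list alone, and a median of -0.66. Rps18 was at -0.72 and Rps8 at -0.66. Mitochondrial respiration genes, 16 tested, had 0 past the threshold over all genes and 5 that fell over the list alone, among them Cox4i1 (-0.66), Uqcrfs1 (-0.62) and Ndufb5 (-0.56), and a camera adjusted p of 0.0642. Fold changes also followed gene length. Leaving out ribosomal protein genes, the median log2 fold change was -0.37 for the 331 protein-coding features of up to 1000 bp, -0.27 for the 1360 of over 1000 and up to 2000 bp, -0.19 for the 3412 of over 2000 and up to 4000 bp and -0.14 for the 4562 longer ones. The 74 ribosomal protein genes had a median of -0.67, below that of each length class. With the sex term this median was -0.40, and those of the length classes -0.27, -0.19, -0.11 and -0.08. Of the 23 lists, 3 passed with the preset correlation of camera, 0 with an estimated one (0 at an unadjusted p under 0.05) and 0 with fry (6 at an unadjusted p under 0.05). With the sex term 11 passed with the preset correlation and 0 with an estimated one.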

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

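Every alternative except the sex term and limma-voom on recovered reads was fixed before the data were examined. Mafb kept its direction and its call under all of them but the sex term, where it was at -3.12 (limma adjusted p = 0.0514, range over alternatives 0.00166 to 0.0514); without single libraries it ranged from -3.82 to -3.31. The 101 called features kept their sign wherever they were tested. The counts of 22 higher and 79 lower did not hold: without single libraries they ranged from 6 to 168 and from 4 to 1160. The highest came without Control 3, the only male Control, where sex and genotype coincide. Other counts beyond 1.5 times were 4 and 5 with the replicate block, 9 and 8 without a filter, 11 and 123 at a mean RPKM of at least 5, 45 and 156 with the proximal tubule covariate, 3 and 2 with the sex term, and, for lower features, 22 after median ratio scaling and 32 after quantile normalization. The sex term and the block cost degrees of freedom, and the strict filter tested 3994 features and no filter 22374; the cause of the other shifts was not tested. The labels do not say whether the numbers pair the mice. Same-numbered mice deviated from their group means with correlations of -0.40, 0.04 and -0.53, which show no pairing. With 3 mice per group and both sexes among the Control mice, these values cannot exclude it.

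The 3 called lists became 5 to 10 without single libraries, 5 after median ratio scaling, 9 without a filter, 9 with the tubule covariate, 11 with the sex term, 5 with limma-voom, and 0 with an estimated correlation or with fry. Some lists changed direction, with these adjusted p: at a mean RPKM of at least 5, podocyte cytoskeleton and identity markers (0.97 each) and distal nephron (0.833); with the tubule covariate, podocyte cytoskeleton (0.441), identity markers (0.440), endothelium (0.441) and antioxidant genes (0.166); with the sex term, podocyte cytoskeleton (0.267), identity markers (0.0355), endothelium (0.930) and antioxidant genes (0.404); without a filter, antioxidant (0.754), retinoid and unfolded protein genes (0.941 each); with fry, which takes no other genes as reference, antioxidant (0.587), fibrosis (0.895), basement membrane and lipid (0.662 each), interferon (0.751), mesangial and unfolded protein (0.728 each) and retinoid genes (0.649). Without Control 2, podocyte cytoskeleton (camera adjusted p = 0.996), identity markers (0.579) and mesangium (0.987) turned. Without Mafb-cKO 1, endothelium (0.711), unfolded protein (0.521) and antioxidant genes (0.968) turned. Distal nephron turned without Control 3 (0.411) and without Mafb-cKO 3 (0.512), and interferon genes without Mafb-cKO 3 (0.573). Ranges over all runs without single libraries, which include those that kept the direction, were wider. They were 0.386 to 0.996 for podocyte cytoskeleton, 0.0600 to 0.692 for identity markers, 0.0378 to 0.896 for endothelium and 0.00992 to 0.987 for mesangium. For distal nephron they were 0.0351 to 0.512, for interferon 0.0248 to 0.713, for unfolded protein 0.0132 to 0.912 and for antioxidant genes 0.199 to 0.968.

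Kap turned from 2.50 to -0.061 with the sex term. Genes with smaller fold changes also turned. Of those given here, Podxl, Slc12a1, Aqp2, Aqp3, Fxyd4, Scnn1g, Umod and Hsd11b2 were outside the naming rule, as were Trpm6 and Tlr7 below. With that term Podxl was at 0.061 (-0.45 without it), Slc12a1 at -0.079 and Aqp2 at -0.29; with the tubule covariate Slc12a1 was at -0.21 and Aqp2 at -0.40; after median ratio scaling Aqp3 was at 0.0034, Fxyd4 at 0.0098 and Scnn1g at 0.035; after quantile normalization Aqp3 was at 0.043, Hsd11b2 at 0.021 and Scnn1g at 0.022. Without single libraries Lyz2 ranged from -0.58 to 1.30, Umod from -0.58 to 0.011, Slc12a1 from -0.041 to 0.33, Aqp2 from -0.34 to 0.44, Aqp3 from -0.45 to 0.11, Scnn1g from -0.38 to 0.17, Fxyd4 from -0.45 to 0.042 and Hsd11b2 from -0.46 to 0.13. Of 34 called genes named, 30 lost their call with the sex term and 25 with the block, 23 without a filter, 8 after median ratio scaling, 6 after quantile normalization (Spon2, H2-Q7, Arhgap24, Pvalb, Trpm6 and Tlr7), 3 with limma-voom and 2 with the tubule covariate. Without single libraries, 24 lost it without Control 1, 11 without Control 2, 0 without Control 3, 13 without Mafb-cKO 1, 24 without Mafb-cKO 2 and 17 without Mafb-cKO 3. Calls kept without Control 3 do not separate genotype from sex, since the 2 coincide there. Depth limits low features: Spon2 in Control rested on a mean of 0.065 RPKM.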

Other observations

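The tests in this part were chosen after the results had been seen, and so were the genes named outside the rule. Rbfox1, a splicing factor gene, rose from 0.103 ± 0.0364 to 1.81 ± 0.160 RPKM (SD, n = 3; limma adjusted p = 0.00536). Nptx1, which encodes neuronal pentraxin, rose from 0.0310 ± 0.0224 to 1.73 ± 0.422 RPKM (limma adjusted p = 0.0103), and Xkr4 rose from 0.167 ± 0.00311 to 1.59 ± 0.177 RPKM (limma adjusted p = 0.00644). Efemp1, an extracellular matrix gene, rose by 1.07 on the log2 scale (limma adjusted p = 0.0410). Among the genes that fell were Pdpn, which encodes the podocyte surface protein podoplanin (20.1 ± 6.11 to 5.99 ± 0.104 RPKM, limma adjusted p = 0.0344), the endosomal receptor gene Tlr7 (7.59 ± 3.71 to 1.27 ± 0.316 RPKM, limma adjusted p = 0.0422) and the autophagy receptor gene Optn (14.6 ± 5.77 to 3.49 ± 0.236 RPKM, limma adjusted p = 0.0335). After median ratio scaling Pdpn was at -1.34, Tlr7 at -1.68 and Optn at -1.54, and the limma adjusted p were 0.0516, 0.0713 and 0.0518 (over all alternatives 0.00166 to 0.172, 0.0153 to 0.418 and 0.00945 to 0.292). Each of these 7 kept its direction with the sex term and had an adjusted p above 0.05 there. The log2 fold changes of the genes that rose hardly moved, from 1.35 to 1.39 for Rbfox1, 1.39 to 1.42 for Nptx1, 1.15 to 1.14 for Xkr4 and 1.07 to 1.10 for Efemp1. Those of the genes that fell became smaller, from -1.54 to -1.02 for Pdpn, -1.84 to -1.30 for Tlr7 and -1.74 to -1.26 for Optn.

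How far sex and not Mafb lies behind the 101 calls was weighed because 2 of 3 Control mice were female, and sex as the whole cause is argued against for Fgl2, Ccdc3, Cyp2s1 and Clic3, the 4 features that passed over all genes with the sex term too. It is also argued against for Mafb, the deleted gene, and Nphs1, which were among 7 genes fixed by name before the data were examined: they went from -3.59 (SE 0.26) to -3.12 (SE 0.29) and from -3.56 (SE 0.27) to -3.08 (SE 0.30), with a limma p of 0.000128 each when adjusted over these 7, and just missed the threshold over all genes. Their unadjusted p rose from 1.59e-06 to 2.87e-05 and from 2.25e-06 to 3.66e-05, and fewer features had a small p with the term (811 against 2913 under 0.05), which also raises the adjusted p. For the other 95 sex and genotype cannot be told apart: their folds kept a median of 0.806 of their size (0.637 to 1.24), but they were chosen with Control 3 as a Control, and with the sex term their adjusted p ran from 0.0598 to 0.471. These values rest on 1 male Control mouse, which the fit takes to vary like the others, and sex may still account for part of any of the differences.

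The real grouping gave 22 features higher and 79 lower, and the other 9 of the 10 splits of the 6 mice gave 0 features in either direction, so that 1 of the 10, the real one, gave as many for either count. For the fixed lists 9 of 10 splits gave at least the real 3, with up to 13 in another split. With 10 splits a share under 0.05 cannot be reached. With an estimated correlation each of the 10 splits, the real one included, called 0 lists, so the higher counts of other splits do not separate a structure of the mice from a preset correlation that is too low for these lists.

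Nphs1 fell far more than most podocyte genes. A lower share of podocytes in the Mafb-cKO isolates would lower podocyte genes together. The other 61 list members had a median log2 fold change of -0.39 (SD 0.53) against -3.56 for Nphs1, and 12 of them were positive. This median does not measure the share, since list genes that other cells also express would fall less. Of the podocyte genes fixed by name, Magi2_1 was at -2.04, Tcf21 at -1.81, Nphs2 at -0.96, Wt1 at -0.86 and Synpo at -0.70. All of these fell, but by less than Nphs1, which argues against a lower share as the whole cause of the Nphs1 fall. Library scaling and sex as the whole cause are argued against as well, since Nphs1 was at -3.36 after quantile normalization (limma adjusted p = 0.00877, range over alternatives 0.00184 to 0.0561) and at -3.08 with the sex term. A lower level of Nphs1 RNA in podocytes that lack Mafb remains a hypothesis that rests on these tests, and whether transcription changed was not measured. Whether podocytes were fewer stays open, since the median of -0.39 lay below the -0.17 of all tested features but not below the -0.56 of the endothelial list, and with the sex term it was -0.13 against -0.11 for all tested features.

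Pvalb and Trpm6, a magnesium channel gene of the distal convoluted tubule (3.94 ± 0.395 to 1.81 ± 0.176 RPKM, SD, n = 3, limma adjusted p = 0.0219), both fell, with a mean log2 fold change of -1.15. Less distal tubule of every segment in the isolates is argued against as the whole cause only in the fit of all 6 mice. There 8 list members of the thick limb and collecting duct had a median of -0.18 (SD 0.21). These were Umod, Slc12a1, Kcnj1, Aqp2, Aqp3, Scnn1g, Fxyd4 and Hsd11b2, while Atp6v1g3 and Slc4a1 of the same list were left out. With the sex term the median of the 8 was -0.64 (SD 0.32) and the mean of the pair -1.21. Trpm6 was then at -0.94, near Kcnj1 (-0.93), Hsd11b2 (-0.85) and Scnn1g (-0.81), so the question stayed open for Trpm6. Pvalb was at -1.48, Umod at -0.65, Aqp3 at -0.63, Aqp2 at -0.29, Fxyd4 at -0.22 and Slc12a1 at -0.08. Whether fewer fragments of the distal convoluted tubule alone explain the falls of Pvalb and Trpm6 was not decided. Slc12a3 was at -0.89 (SE 0.27), less than 1 SE from the mean of the pair. The log2(RPKM + 1) scale, however, understates the change of low genes such as Pvalb and Trpm6. With a pseudocount of 0.1 Pvalb was at -1.95 and Trpm6 at -1.08. In mean RPKM Slc12a3 stood at 0.551 of Control, Trpm6 at 0.460 and Pvalb at 0.251. Both calls were lost after quantile normalization, with Pvalb at -1.34 (limma adjusted p = 0.0592, range over alternatives 0.0217 to 0.292) and Trpm6 at -0.67 (limma adjusted p = 0.0694, range 0.0167 to 0.145), and both folds were then smaller than before (-1.50 and -0.81).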
